A study of Mus musculus with 63 samples.

How the data were processed

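Amplicon bisulfite sequencing of 63 libraries in 21 groups of 3 was analysed from per-CpG files. Per the file headers, the deposited values are counts of all and of methylated calls at each CpG, for both strands together and for each strand, and a fraction of methylated calls. In all 47197 lines of the 63 files the total count equalled the sum of the strands and the fraction equalled methylated over total count to 3 decimals. Reads were trimmed with Trim Galore and handled with SAMtools against mm10, per the submitters' processing notes, which give no versions. The aligner, the methylation caller and non-CpG conversion rates are not given in the sources used here. Libraries were amplified by 27 PCR cycles without molecular identifiers and sequenced on MiSeq, DNBSEQ G400 or Aviti instruments, per the labels' protocols, with the instrument not given per sample, so a sequencing batch was not tested. Reads are therefore not independent molecules. The SDs of methylation values and the SEs of differences in points are between biological replicates.

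CpGs were assigned to the amplicon coordinates of the series text. A CpG was kept in a system (CasTuner, dCas9-KRAB or F121.9) when at least 2 libraries of every group had 20 or more reads there, and a library with under 50% of an amplicon's kept CpGs had no value for it. Percent methylation per library was 100 times methylated over total counts summed over the kept CpGs. In the CasTuner system this rule kept 0 island CpGs, so island values for sgRnf12, sgZic3 and sgZfp280c were taken from fits to the single line, with 23, 23 and 18 CpGs, a choice made after the coverage was seen. The sgZfp36l1 line had no island CpG under the rule and no island value. Minus-strand calls in the upstream amplicon were nearly all methylated in every library, so its plus-strand percentages are given beside those of both strands. The minus-strand share of upstream calls ranged from 6.56% to 44.4% between libraries. No CpG lay in both promoter amplicons.

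Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 odds of methylation with 0.5 added to methylated and unmethylated counts, with a group-means model fitted per system, two-sided. The model was fitted amplicon by amplicon so that missing values are allowed, and was checked against lmFit with eBayes where no value was missing. limma draws the spread of each amplicon towards that of the other amplicons in a fit, which come from the same libraries. In the F121.9 fit and the fits to the sgRnf12 and sgZic3 lines alone, all amplicons received 1 common spread. Their p-values thus treat the amplicons of a library as independent. Benjamini-Hochberg adjustment ran over all amplicons within 13 comparisons of perturbed with control cells, within 7 comparisons of day 4 with day 2 and within 4 interactions of knockdown with day, at an adjusted p of 0.05. Differences in points and their SE come from the percent values. The exact two-sided permutation test of 3 against 3 libraries cannot give a p under 0.1. Single CpGs were tested with the edgeR 4.0.16 quasi-likelihood test on methylated and unmethylated counts with a term per library, adjusted within each comparison. CpGs of an amplicon come from the same libraries and are not independent, while edgeR shares its estimate of spread among them. Its p-values and counts of CpGs therefore do not measure the spread between replicates alone. Named CpGs were up to 3 per amplicon and comparison with the largest difference among those called and without overlap between groups, of which the text gives the first, and CpGs within the YY1 core motif formed a list. Comparisons, tests, filter and naming rule were fixed before the data were examined. The target genes are not measured by this assay, so knockdown was not checked.

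The tests were tried on simulated counts drawn from the real means and depths. For sgZfp281 at day 2 (48 CpGs), 76% of 200 CpGs changed by 1 log2 odds were recovered and 9 of 760 unchanged CpGs were called. For RNF12-KO against WT (43 CpGs), 22.8% were recovered at 1 log2 odds and 83.3% at 2. For sgRnf12 at day 3 (25 CpGs), 16% were recovered at 1 log2 odds and 66% at 2.

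Alternatives set before the data were seen were coverage minimums of 10 and 100 reads, the replicate number as a block, an unweighted mean over CpGs, the percent scale, 1 fit over all 63 libraries, fits to single CasTuner lines, limma in place of edgeR for CpGs, and leaving out each library. Plus-strand calls alone, and leaving out amplicons under 1% of the reads of the library's deepest amplicon, were added after the data were seen. The latter was first run over all 4 Xist amplicons and then, after its results were seen, over the YY1, start-site and upstream amplicons, and both versions are reported. Same-numbered libraries deviated together, with every correlation over 0.1, in 2 of 13 comparisons, for which blocked values are given beside the results. Figures were drawn with matplotlib 3.10.9.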

Results

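DNA methylation was measured at the 5' end of Xist, the noncoding RNA gene whose expression silences 1 X chromosome in female mammals, in 63 amplicon bisulfite libraries from differentiating female mouse embryonic stem cells. Bisulfite treatment converts unmethylated cytosine, so the share of reads that still carry C at a CpG is its methylation level. The libraries formed 21 groups of 3 biological replicates. TX1072 cells, a CAST x C57BL/6 hybrid line, carried either the CasTuner system, in which a guide RNA represses its target once the compound dTAG-13 is removed, or a split dCas9-KRAB repressor assembled with abscisic acid (ABA). CasTuner knockdowns (KD) were compared with the same line kept in 500 nM dTAG-13, and dCas9-KRAB knockdowns with a line carrying safe-targeting control guides (sgSTC). No CasTuner line carried a control guide, so removal of dTAG-13 is not told apart from the knockdown. Differences between lines are likewise not told apart from the guide in dCas9-KRAB or the genotype in F121.9. F121.9 cells, another hybrid line, were wild type (WT), lacked Rnf12 (RNF12-KO) or lacked both Rnf12 and Rex1 (DKO).

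The 4 Xist amplicons lie on chromosome X of the mm10 build. The YY1 amplicon (103481727 to 103482006, 9 CpGs) and the CpG island amplicon (103482019 to 103482381, 23 CpGs) cover the promoter-proximal element RE57 inside exon 1 of Xist, which spans 103473716 to 103483254 on the minus strand. The start-site amplicon (103483101 to 103483344, 10 CpGs) contains the annotated Xist start at 103483254, and the CpGs of the upstream amplicon (103483289 to 103483491, 6 CpGs) lie beyond it, from 103483377 to 103483455. All 4 fall within exon 4 of Tsix, the antisense gene on the plus strand, which runs from 103481275 to 103484957. Major satellite repeats, sequences of pericentromeric heterochromatin, formed the fifth target and served as a measure of methylation away from Xist. Total CpG calls per library ranged from 1693 to 58205960, with a median of 1190938. The median over libraries of the median reads per CpG was 12242 in the YY1 amplicon, 986 in the island, 23578 in the start-site amplicon, 83173 in the upstream amplicon and 8.5 in the satellites, whose calls were summed over many CpGs.

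**Figure D1:**
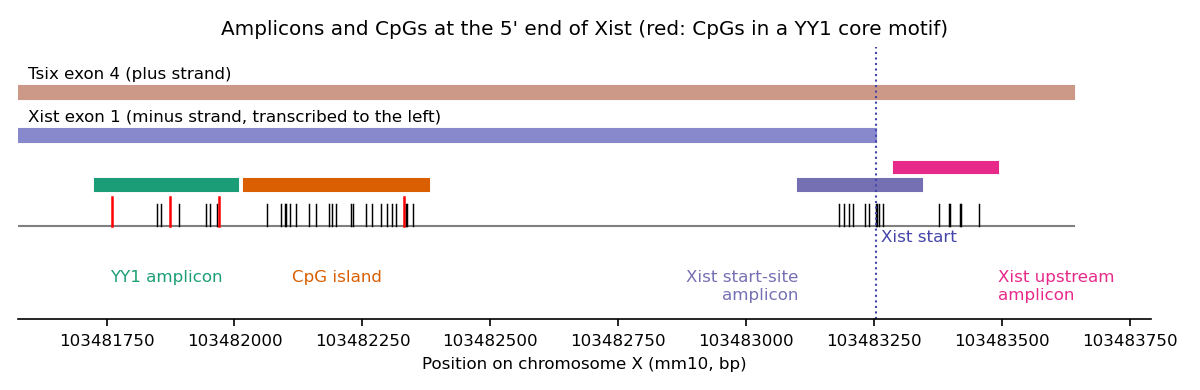
Map of the 5' end of Xist on chromosome X (mm10, x axis in bp), with the 4 amplicons as coloured bars, their CpGs as ticks on the line (red inside a YY1 core motif), and the Xist and Tsix exons as bars above. The YY1 amplicon and the island lie inside Xist exon 1, and the start-site amplicon spans the Xist start at 103483254.

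The first comparison asked how loss of RNF12, an X-linked ubiquitin ligase that activates Xist by marking the repressor REX1 for degradation, alters methylation of these elements at day 3 of differentiation, after 7 days of induction. Island methylation rose from 44.6% ± 3.99 (SD, n = 3) in the control to 67.1% ± 3.21 (SD, n = 3) in the sgRnf12 knockdown, a difference of 22.4 ± 2.95 points (SE; limma adjusted p = 2.25e-07 in the fit to this line alone, higher in 3 of 3 libraries). The start-site amplicon rose from 57.5% ± 4.46 to 76.9% ± 2.77 (adjusted p = 0.0285), and the satellites from 79.8% ± 1.25 to 84.4% ± 1.13 (adjusted p = 0.00703). In log2 odds the satellite rise was 0.461, beside 1.30 at the start site and 1.34 in the island. Whether a shift beyond Xist contributed to the Xist rises was not tested. In the YY1 amplicon methylation was 62.0% ± 0.781 in the knockdown and 36.9% ± 2.89 in the control, and in the upstream amplicon 85.9% ± 1.33 and 74.2% ± 2.48. The groups did not overlap in either.

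These last 2 differences did not pass the test in the fit over all CasTuner lines (adjusted p = 0.129 and 0.0895), in which the YY1 residual SD was 0.985 log2 odds, against 0.13 in the sgRnf12 line and 1.65 in the sgZfp36l1 line. With the spread taken from the sgRnf12 line alone, the adjusted p was 5.17e-08 for the YY1 amplicon, 2.67e-07 for the start site and 3.2e-06 for the upstream amplicon. From plus-strand calls alone, the upstream amplicon was at 79.1% ± 1.63 against 66.0% ± 2.63. Of 25 CpGs tested outside the island by edgeR's quasi-likelihood test, 10 rose and 0 fell, 9 of them in the start-site amplicon, with 17 at an unadjusted p under 0.05 and 0 called by limma. In the fit to this line alone, all 48 CpGs of the 4 amplicons rose. In the start-site amplicon the largest rise was at 103483259, from 50.0% ± 4.78 to 72.6% ± 3.18 (adjusted p = 0.0216), and in the line fit the largest rise in the island was at 103482269, from 40.3% ± 4.29 to 66.1% ± 3.66 (adjusted p = 1.42e-10). The single upstream CpG that passed, 103483455, went from 27.8% to 48.3% on both strands but from 9.67% ± 1.23 to 17.2% ± 0.84 on the plus strand.

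Same-numbered sgRnf12 libraries deviated together, and with the replicate number as a block the start-site call was lost (adjusted p = 0.0678) and the count of CpGs went from 10 to 0. The start-site call was also lost without knockdown replicate 1 or 3 or control replicate 1 or 2, the largest adjusted p being 0.0887, and each of those runs left 0 CpGs called. These runs used the fit over all CasTuner lines. The island was fitted in the sgRnf12 line alone, where it kept its call in every such run, so the 2 amplicons are not compared on this point.

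The second comparison concerned Zic3, which encodes an X-linked zinc-finger transcription factor, at the same time point. The satellites fell, from 80.8% ± 1.58 in the control to 70.0% ± 2.18 in the sgZic3 knockdown, a difference of -10.9 ± 1.55 points (SE; limma adjusted p = 6.54e-06, lower in 3 of 3 libraries). Start-site methylation was 74.2% ± 1.59 in the knockdown and 63.2% ± 4.26 in the control, without overlap, and missed the threshold in the fit over all CasTuner lines (adjusted p = 0.228) while passing it in the fit to this line alone (adjusted p = 0.0113). YY1 amplicon values were 40.1% ± 2.83 and 42.2% ± 4.85 and island values 56.1% ± 2.61 and 57.1% ± 10.1. Upstream values were 81.3% ± 2.47 and 78.4% ± 3.7 (plus strand 74.4% ± 2.69 and 70.2% ± 3.93), and none of these 3 amplicons passed the test (adjusted p from 0.737 to 0.909). Without control replicate 3 the YY1 difference turned to 0.208 points and the island difference to 3.74, and the island difference was also positive without knockdown replicate 1. No CpG passed edgeR's test over the CasTuner lines (0 of 25, with 0 at an unadjusted p under 0.05 and 0 by limma), and 9 of 48 rose in the line's own fit.

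The Zfp36l1 knockdown, which targets a gene for an RNA-binding protein of mRNA decay, was measured at days 2 and 4. At day 2 the YY1 amplicon was at 41.7% ± 30.6 in the knockdown and 41.6% ± 5.83 in the control, and the start site at 65.3% ± 8.47 and 69.1% ± 6.78. The upstream amplicon was at 48.0% ± 2.22 and 55.0% ± 5.85 (plus strand 41.0% ± 1.75 and 47.5% ± 5.15), and the satellites at 76.8% ± 0.95 and 77.6% ± 2.27. None of these differences passed the test (adjusted p from 0.58 to 0.963). The YY1 difference turned to -17.5 points without knockdown replicate 3 and was also negative without control replicate 2, and the satellite difference to 0.522 points without control replicate 1. At day 4 the start-site amplicon was lower in the knockdown, at 76.0% ± 7.57 against 84.8% ± 14.6, with a limma adjusted p of 0.0474 and overlapping groups. YY1 values were 75.9% ± 30.7 and 93.9% ± 1.76 (adjusted p = 0.109). Upstream values were 71.2% ± 25.3 and 85.4% ± 1.74 (adjusted p = 0.126; plus strand 62.99% ± 26.3 and 77.3% ± 2.17), and satellite values 89.2% ± 0.712 and 89.7% ± 0.537.

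Single libraries stood apart in these groups. YY1 methylation was 40.5% in day 4 knockdown replicate 1 and 93.0% and 94.3% in the other 2 libraries, and upstream methylation was 42.0% in day 4 knockdown replicate 3 and 85.7% and 85.9% in the others. Start-site methylation was 68.1% in day 4 control replicate 3, from a median of 59.5 reads per CpG, and 92.0% and 94.5% in the others. At day 2, knockdown replicate 3 stood at 76.9% in the YY1 amplicon, from 68 reads per CpG, against 21.6% and 26.5%. The start-site call at day 4 was lost without knockdown replicate 1 or 2 or control replicate 1 or 2, with -3.99 points as the smallest difference. Without control replicate 3 the start-site difference was the largest, at -17.2 points. The call did not hold in further settings. It was lost with a replicate block (adjusted p = 0.0921), on the percent scale (adjusted p = 0.2) and in the fit to the line alone (adjusted p = 0.234). The difference was -0.679 points (adjusted p = 0.627) once amplicons with under 1% of the reads of the library's deepest amplicon were left out, a setting chosen after seeing the data. Without knockdown replicate 2 or 3 the YY1 difference passed the test, and without replicate 1 it was -0.233 points. Without knockdown replicate 1 or 2 the upstream difference passed, and without replicate 3 it turned to 0.42 points. Counts of CpGs moved likewise. edgeR called 9 of 25 CpGs at day 4, all lower and all in the start-site amplicon, limma called 0, and the count was 0 with a replicate block and 0 in the fit to the line alone. It was 0 without knockdown replicate 1 or control replicate 1 or 2, 23 without knockdown replicate 2 and 19 without knockdown replicate 3. At day 2 edgeR called 0 of 25 CpGs, with 0 at an unadjusted p under 0.05 and 0 by limma. The knockdown effect did not differ detectably between the days in any amplicon (interaction adjusted p from 0.282 to 0.964), but without day 4 control replicate 3 the start-site interaction was -13.4 points and passed the test, and without day 4 knockdown replicate 3 the upstream interaction turned to 7.4 points. The satellite interaction turned to -1.03 points without day 2 control replicate 1 and was also negative without day 2 knockdown replicate 2.

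For Zfp280c, which encodes a zinc-finger protein, the Xist amplicons did not differ detectably between knockdown and control. At day 2 YY1 values were 51.0% ± 4.4 and 61.1% ± 11.1 and start-site values 74.0% ± 7.2 and 75.5% ± 6.56. Upstream values were 63.4% ± 3.16 and 70.3% ± 11.2 (plus strand 54.7% ± 3.2 and 61.7% ± 11.5), and island values 82.3% ± 3.28 (n = 3) and 85.2% ± 3.29 (n = 2). At day 4 all 4 amplicons lay above 90% in both groups. YY1 was at 92.5% ± 1.1 and 93.3% ± 0.922 and the island at 96.9% ± 0.494 and 95.5% ± 1.92. The start site was at 95.6% ± 0.299 and 96.2% ± 0.521 and the upstream amplicon at 92.7% ± 1.68 and 92.6% ± 3.34 (plus strand 87.6% ± 2.77 and 87.4% ± 5.28). Without control replicate 3 the day 2 difference shrank from -10.1 to -3.84 points in the YY1 amplicon and from -6.91 to -0.47 points upstream. The start-site difference at day 2 turned to 2.57 points without knockdown replicate 3 and was also positive without control replicate 1 or 2. The upstream difference at day 4 turned to -1.88 points without control replicate 1 and was also negative without knockdown replicate 2. The satellites were lower in the knockdown at day 4, 82.7% ± 2.45 against 86.4% ± 1.6 (limma adjusted p = 0.0161, exact permutation p = 0.2, groups overlapping). This call was lost without knockdown replicate 2 or 3, without control replicate 1, and in the fit to the line alone (adjusted p = 0.16). At day 2 the satellites were at 78.5% ± 1.57 and 79.9% ± 1.09. edgeR called 0 of 25 CpGs at day 2 and 0 of 25 at day 4, with 0 at an unadjusted p under 0.05 and 0 by limma on both days, and the interaction with day passed in no amplicon (adjusted p from 0.271 to 0.912). The start-site interaction turned to -3.18 points without day 2 knockdown replicate 3 and was also negative without day 2 control replicate 1 or 2.

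**Figure D2:**
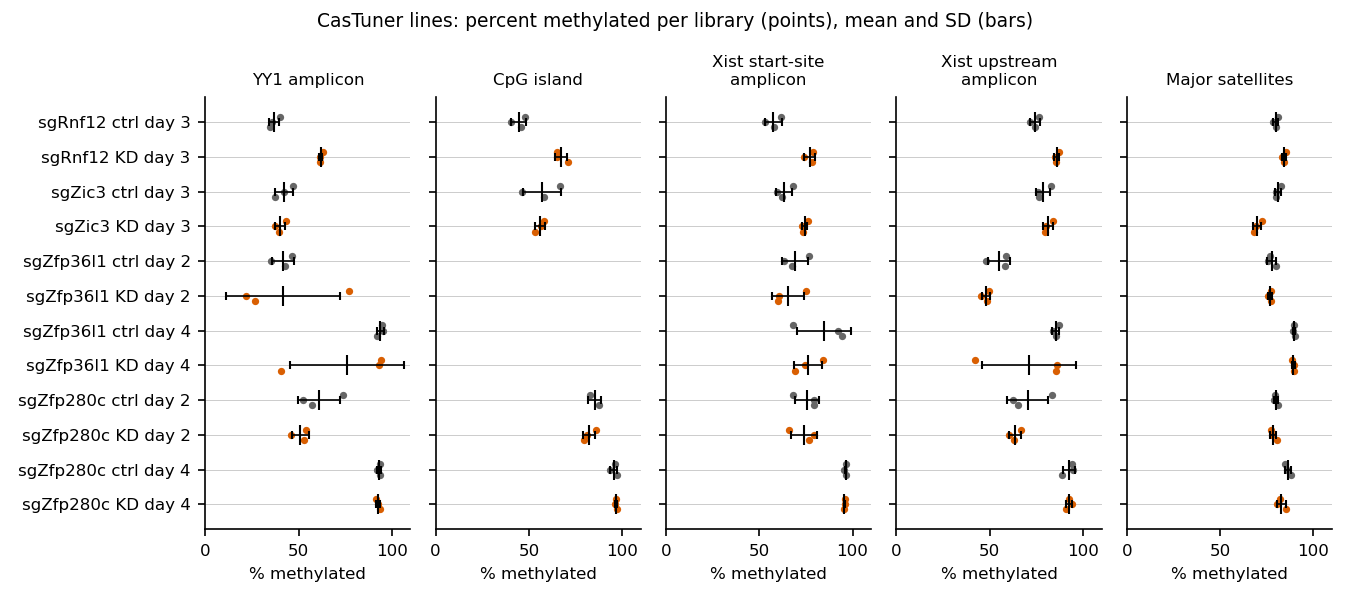
Percent methylated CpG calls (x axis) per library (points) in the 12 CasTuner groups (rows; controls grey, knockdowns orange), with the mean and SD over the libraries of a group, for the 4 Xist amplicons and the satellites. The 3 sgRnf12 knockdown libraries lie between 61.5% and 62.9% in the YY1 amplicon, above controls at 34.5% to 40.1%, and the wide bars of the sgZfp36l1 groups come from single libraries.

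The dCas9-KRAB lines addressed Zfp281 and Rex1, zinc-finger genes active in pluripotent cells, Rex1 encoding the Xist repressor that RNF12 marks for degradation. At day 2 the sgZfp281 knockdown was lower than sgSTC in all 4 Xist amplicons. The YY1 amplicon stood at 9.92% ± 0.605 against 24.2% ± 0.917 (difference -14.3 ± 0.634 points, SE; limma adjusted p = 1.69e-10). The island was at 26.8% ± 1.72 against 48.2% ± 2.23 (-21.4 ± 1.62, adjusted p = 5.98e-10). The start site was at 36.1% ± 1.36 against 54.3% ± 0.881 (-18.2 ± 0.933, adjusted p = 3.57e-07), and the upstream amplicon at 43.4% ± 1.03 against 60.9% ± 0.437 (-17.4 ± 0.645, adjusted p = 3.92e-09; plus strand 39.3% ± 0.929 against 54.1% ± 0.223). Each was lower in 3 of 3 libraries. Satellites were at 55.5% ± 2.86 and 56.6% ± 2.91 (adjusted p = 0.737), a difference that turned to 0.373 points without knockdown replicate 3 and was also positive without control replicate 1. All 48 CpGs fell by edgeR's test, most at 103482287 in the island, from 62.98% ± 3.5 to 36.8% ± 2.62 (adjusted p = 2.85e-20). The largest falls elsewhere were at 103481965 in the YY1 amplicon, from 37.9% ± 1.16 to 17.1% ± 1.36, and at 103483268 in the start-site amplicon, from 63.5% ± 0.984 to 42.9% ± 2.9. Upstream it was at 103483398, from 69.2% ± 0.784 to 48.4% ± 1.65 on both strands and from 63.1% ± 0.652 to 44.0% ± 1.61 on the plus strand.

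At day 4 the sgZfp281 differences were smaller. The YY1 amplicon was at 67.4% ± 2.76 against 73.9% ± 3.22 (adjusted p = 0.00387) and the island at 87.5% ± 0.489 against 90.0% ± 1.05 (adjusted p = 0.0138), both lower. The start site at 74.9% ± 1.58 against 75.6% ± 3.65, the upstream amplicon at 82.3% ± 0.798 against 82.6% ± 0.527 (plus strand 74.5% ± 0.846 against 74.3% ± 0.545) and the satellites at 80.6% ± 0.628 against 79.2% ± 2.05 differed by less than the spread between replicates, and the start-site difference turned to 0.876 points without control replicate 3. Of 48 CpGs, 14 fell and 1 rose, with 7 of the falls in the YY1 amplicon and 7 in the island. The island call was lost without knockdown replicate 1 or control replicate 1 and on the percent scale (adjusted p = 0.182), and the count of CpGs fell to 9 without knockdown replicate 1 and 8 without knockdown replicate 3.

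The sgRex1 knockdown was higher than sgSTC at day 2. The upstream amplicon rose to 74.1% ± 1.3 (difference 13.2 ± 0.794 points, SE; limma adjusted p = 5.81e-08; plus strand 66.6% ± 1.43). The start site rose to 63.6% ± 0.685 (9.33 ± 0.644, adjusted p = 0.00179) and the island to 56.4% ± 2.51 (8.25 ± 1.94, adjusted p = 0.00175). The YY1 amplicon rose to 28.8% ± 1.64 (4.56 ± 1.09, adjusted p = 0.0285), and each rise was seen in 3 of 3 libraries. The YY1 call was lost without knockdown replicate 1 or 3 or control replicate 1. The satellites were at 54.2% ± 3.54 (adjusted p = 0.433). edgeR called 38 of 48 CpGs, all higher, with the largest rise at 103483419 in the upstream amplicon, from 52.8% ± 0.309 to 69.1% ± 1.84 on both strands (adjusted p = 3.37e-24) and from 44.6% ± 0.407 to 60.0% ± 2.06 on the plus strand. On the plus strand alone the largest upstream rise was at 103483417, from 54.7% ± 0.466 to 70.9% ± 1.93. At day 4 the start-site amplicon lay below the control, at 66.3% ± 5.23 against 75.6% ± 3.65 (difference -9.32 ± 3.68 points, adjusted p = 0.000375, exact permutation p = 0.2, the groups overlapping), and all 10 of its CpGs were lower. YY1 at 71.3% ± 2.31, the island at 89.6% ± 1.19, the upstream amplicon at 84.1% ± 1.48 (plus strand 76.2% ± 1.88) and the satellites at 78.9% ± 2.16 did not pass the test. The upstream difference passed without knockdown replicate 2 (2.29 points) and the YY1 difference without control replicate 2 (-4.24 points). Without control replicate 1 the island difference turned to 0.0616 points, and the satellite difference turned to 0.998 points without knockdown replicate 3 and was also positive without control replicate 1 or 2.

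The knockdown effects at day 2 and day 4 differed by the interaction test in all 4 Xist amplicons for both genes. The sgRex1 effect changed by -7.13 points in the YY1 amplicon (adjusted p = 0.0132), -8.63 in the island (adjusted p = 0.00944). It changed by -18.6 at the start site (adjusted p = 1.06e-05) and -11.7 upstream (adjusted p = 8.12e-05). The sgZfp281 effect changed by 7.79, 18.9, 17.5 and 17.1 points (adjusted p from 4.88e-06 to 8.12e-05). Satellite effects did not differ detectably between days (adjusted p = 0.62 for sgRex1 and 0.441 for sgZfp281). When 1 fit over all 63 libraries supplied the spread, none of these interactions passed (adjusted p from 0.293 to 0.671), nor did the 4 sgRex1 Xist differences at day 2, the sgRex1 start-site difference at day 4, the upstream sgZfp281 difference at day 2 or the YY1 and island sgZfp281 differences at day 4. The residual SD of the YY1 amplicon was 0.156 log2 odds among the dCas9-KRAB libraries and 0.985 among the CasTuner libraries. Without day 4 control replicate 3, the sgRex1 interaction in the YY1 amplicon missed the threshold (adjusted p = 0.0504).

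**Figure D3:**
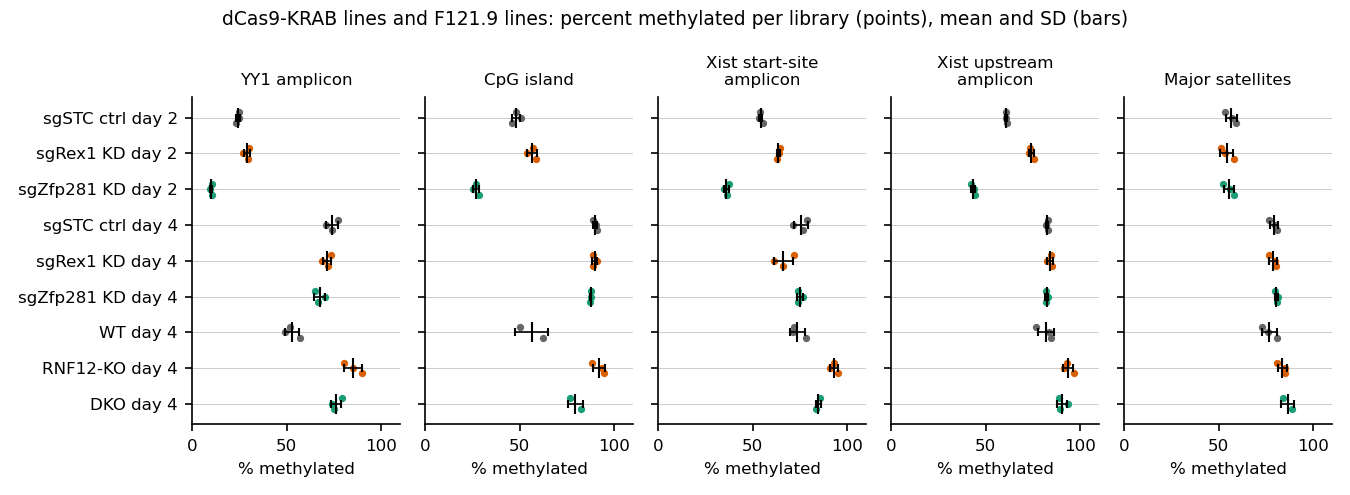
Percent methylated CpG calls (x axis) per library (points) in the 6 dCas9-KRAB groups and 3 F121.9 groups (rows; controls and WT grey, sgRex1 and RNF12-KO orange, sgZfp281 and DKO green), with the mean and SD over the libraries of a group, for the 4 Xist amplicons and the satellites. At day 2 sgZfp281 libraries lie below and sgRex1 libraries above the sgSTC control in the Xist amplicons, where RNF12-KO also lies above WT.

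The F121.9 lines compared deletion of Rnf12, alone or with Rex1, with the wild type at day 4. RNF12-KO was higher than WT in all 4 Xist amplicons and in all 43 CpGs tested. The island rose from 56.3% ± 8.66 (n = 2) to 92.1% ± 3.29 (n = 3), a difference of 35.8 ± 6.41 points (SE; limma adjusted p = 2.14e-07). The YY1 amplicon rose from 52.7% ± 3.87 to 85.2% ± 4.7 (32.5 ± 3.51 points, SE; adjusted p = 3.31e-06). The start site rose from 73.7% ± 4.07 to 93.1% ± 2.09 (19.4 ± 2.64, adjusted p = 6.54e-06). The upstream amplicon rose from 81.7% ± 4.25 to 93.8% ± 2.61 (12.1 ± 2.88, adjusted p = 0.000155; plus strand 73.6% ± 4.36 to 89.7% ± 4.25), and none of these groups overlapped. Satellites were at 76.7% ± 3.99 in WT and 83.8% ± 2.35 in RNF12-KO (adjusted p = 0.155). Their log2 odds difference was 0.645, beside 1.84 upstream, 2.29 at the start site, 2.42 in the YY1 amplicon and 3.24 in the island. A contribution of a shift beyond Xist was not tested here. At the Xist start itself, the CpG at 103483254 rose from 57.6% ± 5.71 to 80.8% ± 4.76 (adjusted p = 9.8e-07), and the largest rise was at 103482098 in the island, from 51.8% to 97.3% (n = 2 in each group).

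In the 4 Xist amplicons the DKO means lay between those of the other genotypes. Against RNF12-KO it was lower in the island, at 79.4% ± 4.06 (n = 2; difference -12.7 points, adjusted p = 0.00169). It was also lower at the start site, at 84.7% ± 1.33 (n = 2; -8.41 points, adjusted p = 0.00948), and in the YY1 amplicon, at 76.2% ± 2.76 (n = 3; -9.02 points, adjusted p = 0.0478). The upstream amplicon, at 90.5% ± 2.63 (plus strand 85.0% ± 4.86), and the satellites, at 86.5% ± 3.52 (n = 2), did not pass (adjusted p = 0.105 and 0.580). Against WT, DKO was higher in the YY1 amplicon (23.5 points, adjusted p = 0.00125), the island (23.1 points, adjusted p = 0.00471) and the upstream amplicon (8.85 points, adjusted p = 0.0153). The start site and the satellites were 10.96 and 9.78 points higher, just short of the threshold (adjusted p = 0.0521 for both). Both passed without WT replicate 2 (adjusted p = 0.042 for both). In log2 odds the satellites rose by 0.970, beside 0.971 at the start site, 1.10 upstream, 1.53 in the YY1 amplicon and 1.59 in the island. At the start site and upstream a change particular to Xist is therefore not told apart from a shift beyond it. edgeR called 39 of 43 CpGs higher in DKO than in WT and 37 of 43 lower in DKO than in RNF12-KO, and limma called 28 and 36. The largest fall against RNF12-KO was at 103482338 in the island, from 90.2% ± 6.86 (n = 3) to 72.0% ± 5.96 (n = 2).

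Depth limits these lines, since DKO replicate 3 held 1693 calls, WT replicates 2 and 3 held 7114 and 9687, and DKO replicate 2 held 58205960. The YY1 call of DKO against RNF12-KO was lost in 5 of 6 runs that left out a library, all but that without RNF12-KO replicate 4, and the start-site call without DKO replicate 2 (adjusted p = 0.0883) and on the percent scale (adjusted p = 0.0554). The DKO against WT calls were lost without DKO replicate 2 or WT replicate 4 in the island and without DKO replicate 3 or WT replicate 4 upstream. Both groups had 2 libraries in the island, and DKO had 2 at the start site, so such a run left 1 library, assumed to vary like the other groups. The count of CpGs called in DKO against WT fell to 16 without WT replicate 4. The count against RNF12-KO fell to 23 without DKO replicate 2 and 13 without DKO replicate 4. With a coverage minimum of 100 reads 24 CpGs were tested, of which 24 were called for RNF12-KO against WT, 20 for DKO against WT and 22 for DKO against RNF12-KO. No CpG that was called at 20 reads and still tested lost its call. At that minimum the YY1 call of DKO against RNF12-KO (adjusted p = 0.129) and the upstream call of DKO against WT (adjusted p = 0.175) were lost. All amplicons of the main F121.9 fit shared 1 spread. The upstream residual SD, 0.555 log2 odds, was above those of the other amplicons (0.325 to 0.537). The upstream p-values in these lines therefore lean on the other amplicons of the same libraries. Same-numbered DKO and WT libraries deviated together, and with the replicate number as a block the satellite difference passed (adjusted p = 0.0222) while no other call of DKO against WT changed.

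**Figure D4:**
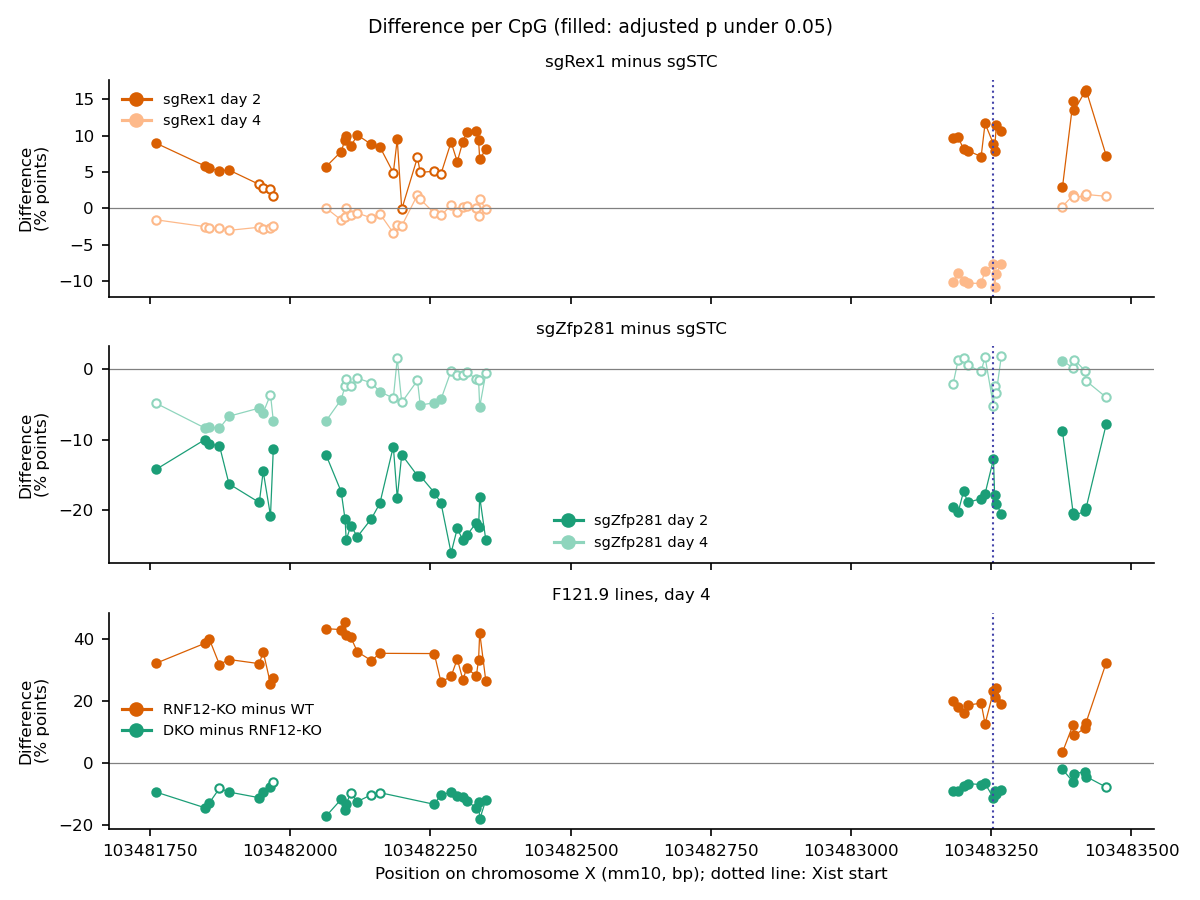
Difference in mean percent methylation per CpG (y axis, percentage points) against position on chromosome X (x axis, mm10, bp) for sgRex1 and sgZfp281 against sgSTC at days 2 and 4 and for RNF12-KO against WT and DKO against RNF12-KO at day 4, with filled points for CpGs with an edgeR adjusted p under 0.05. All 48 CpGs lie below 0 for sgZfp281 at day 2, and all 43 above 0 for RNF12-KO against WT.

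Mean methylation rose between day 2 and day 4 in every line measured on both days. As exceptions, the start-site rise did not pass the test in the sgRex1 and sgZfp36l1 knockdowns. In sgSTC the YY1 amplicon went from 24.2% ± 0.917 to 73.9% ± 3.22, a rise of 49.7 ± 1.93 points (SE; limma adjusted p = 8.94e-19). The island rose by 41.8 points to 90.0% ± 1.05 and the start site by 21.3 points to 75.6% ± 3.65. The upstream amplicon rose by 21.8 points to 82.6% ± 0.527 and the satellites by 22.6 points to 79.2% ± 2.05. In sgZfp281 the rises were 57.5 points in the YY1 amplicon, 60.7 in the island, 38.8 at the start site and 38.8 upstream. In sgRex1 they were 42.6, 33.2 and 10.0 points in the YY1 amplicon, the island and the upstream amplicon. The satellites rose by 25.1 points in sgZfp281 and 24.8 in sgRex1. In log2 odds the satellite rise in sgSTC was 1.55, beside 1.39 at the start site and 1.61 upstream. In sgRex1 it was 1.67, beside 0.178 and 0.889, and in sgZfp281 1.74, beside 2.40 and 2.59. YY1 and island rises were larger, at 2.63 to 4.26. In sgSTC and sgRex1 a rise particular to Xist at the start site and upstream is thus not told apart from a shift beyond it. The sgRex1 start site was the exception, at 63.6% ± 0.685 and 66.3% ± 5.23 (adjusted p = 0.21), and passed the test without day 4 replicate 2 (5.19 points), while without day 4 replicate 3 it turned to -0.0267 points. In the sgZfp280c control the YY1 amplicon rose by 32.1 points to 93.3% ± 0.922 and the island by 10.3 points to 95.5% ± 1.92, and in the sgZfp36l1 control the YY1 amplicon rose by 52.3 points to 93.9% ± 1.76. In all, 31 of 33 tests passed, all of them higher at day 4. The other exception was the sgZfp36l1 knockdown start site (10.7 points, adjusted p = 0.12), which passed without day 2 replicate 3 (15.6 points). The satellite rise in the sgZfp280c knockdown (4.21 points, adjusted p = 0.00734) was lost without day 4 replicate 1 (2.85 points), from plus-strand calls alone (adjusted p = 0.12) and in the fit to the line alone (adjusted p = 0.096). The YY1 rise in the sgZfp36l1 knockdown was lost in its own line fit (adjusted p = 0.0501). Its values overlapped between the days (exact permutation p = 0.2). The days also overlapped upstream in that knockdown (exact permutation p = 0.4), where day 4 replicate 3 was at 42.0%. They overlapped as well at the start site of the sgZfp36l1 control (exact permutation p = 0.2).

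The 4 CpGs inside the YY1 core motif formed a list fixed in advance, of which 3 lie in the YY1 amplicon and 1, at 103482332, in the island. The 3 core CpGs of the YY1 amplicon lie at 103481761, 103481874 and 103481970. Their summed counts gave lower methylation than those of the other 6 CpGs of that amplicon in 63 of 63 libraries. The median difference was -5.08 points. The difference was largest at 103481970, with a median of -8.27 points and lower values in 63 of 63 libraries. It was -4.56 points at 103481874 (lower in 61 of 63) and -2.83 points at 103481761 (lower in 53 of 63). Without 103481970 the other 2 were lower in 63 of 63, by a median of -3.33 points. Single CpGs outside the motif did not all lie above the core CpGs. In the sgZfp36l1 control at day 2, 103481848 averaged 31.3%, below the core CpGs at 35.7%, 37.0% and 31.8%. In the sgRnf12 control it averaged 35.4%, among core CpGs at 38.4%, 35.0% and 27.5%. All libraries measure the same positions, so the tally over libraries does not show whether the motif accounts for the difference. The core CpG of the island was instead higher than the other 22 island CpGs in 36 of 47 libraries, with a median difference of 2.51 points. It was higher in 18 of 18 dCas9-KRAB libraries and in 6 of 6 of the sgZic3 line, but in 4 of 6 of sgRnf12, 5 of 11 of sgZfp280c and 3 of 6 F121.9 libraries. In sgSTC at day 2 the core CpGs of the YY1 amplicon were at 20.4% ± 1.05 and the others at 26.2% ± 0.856, and in sgZfp281 at 8.16% ± 0.587 and 10.8% ± 0.659. In the F121.9 lines these core CpGs went from 49.4% ± 3.93 in WT to 80.4% ± 5.74 in RNF12-KO, and the others from 55.3% ± 4.89 to 88.8% ± 3.56.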

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

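All tests of technical explanations in this part were chosen after the result was seen, while the interaction tests themselves were planned. The knockdown effect at day 4 minus that at day 2 passed the interaction test in every Xist amplicon of both dCas9-KRAB knockdowns. For sgRex1 it was -7.13 points in the YY1 amplicon, -8.63 in the island, -18.6 at the start site and -11.7 upstream. For sgZfp281 it was 7.79, 18.9, 17.5 and 17.1 points in the same order.

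The median ratio of the log2 odds difference at day 4 to that at day 2 over the 8 effects was 0.0468. The interactions were called on that same scale, so the ratio restates them and is no separate test. An upper limit of the percent scale would compress differences in points but not in log2 odds. The interactions passed in log2 odds in all 4 Xist amplicons of both knockdowns (limma adjusted p from 4.88e-06 to 0.0132). That limit alone would thus not give them if effects were constant in log2 odds, which was not tested, so the question is not decided. A plateau below full methylation that compresses differences at day 4 stays open, untested. Incomplete conversion or a genome-wide shift at day 2 would move the satellites by at least 50% of the Xist difference in the same direction, and the ratio was 0.0548 (SE 0.106) for sgZfp281 and -0.275 (SE 0.246) for sgRex1. The sgRex1 ratio lay outside the narrower bound set for the absence of a shift, in the opposite direction, so this test argues against a shared shift of the needed size and not against any satellite change. Plus-strand calls alone kept 0.852 of the upstream difference for sgZfp281 and 0.946 for sgRex1, so minus-strand calls were not its only source. The minus-strand share of upstream calls at day 2 was 6.56% to 7.05% in sgZfp281 and 14.4% to 15.4% in sgSTC. In sgRex1 it was 21.4% to 23.0%. The share thus differed between groups, and whether plus-strand values are themselves free of bias was not tested. A biological change of the knockdown effect between days stays open beside a plateau, untested. The instrument of each library is not given, so a batch that parted knockdown from control libraries within a day was not tested, and no interaction passed in 1 fit over all libraries (adjusted p from 0.293 to 0.671).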

How the results depend on the processing

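The tests from plus-strand calls alone and without amplicons of low relative depth, in both versions, were chosen after the result was seen. Values are differences in points or counts of CpGs, and the cause of each change was not tested, except where fewer CpGs were tested. All other results under each setting kept their direction and their side of the threshold where they had a value. Excluding the CpGs shared by the promoter amplicons changed nothing, since there were none. At a coverage minimum of 100 reads the sgZfp280c and F121.9 island results had no value, and 12 island results had none when the island was included in the rule on relative depth. Depth left the sgZfp36l1 line without an island value, and a run that left an arm with 1 library assumes that it varies like the other groups.

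With a coverage minimum of 10 reads, a call was gained for DKO against WT start (11), DKO against WT satellite (12), DKO against RNF12-KO upstream (-4.3). With a coverage minimum of 100 reads, the call was lost for DKO against WT upstream (5.28), DKO against RNF12-KO YY1 (-7.93). Gained calls were sgZfp36l1 KD day 4 against day 2 start (10.7), sgZfp36l1 interaction start (-13.4), DKO against WT satellite (13.2), DKO against RNF12-KO upstream (-4.55). The sign changed for sgZfp36l1 day 2 YY1 (-17.5). The counts of CpGs were 22 for DKO against RNF12-KO, 20 for DKO against WT, 24 for RNF12-KO against WT, out of 24 tested in place of 43. With the replicate number as a block, the call was lost for sgRnf12 day 3 start (19.4), sgZfp36l1 day 4 start (-8.81). A call was gained for sgZfp280c interaction satellite (-2.31), DKO against WT satellite (9.78), DKO against RNF12-KO upstream (-3.24). The counts of CpGs were 0 for sgRnf12 day 3, 0 for sgZfp36l1 day 4. With an unweighted mean over CpGs, a call was gained for DKO against WT start (10.9). The sign changed for sgZfp280c day 4 upstream (-0.183), sgZfp36l1 interaction satellite (-0.395). On the percent scale, the call was lost for sgZfp36l1 day 4 start (-8.81), sgZfp281 day 4 island (-2.5), DKO against RNF12-KO start (-8.41). Gained calls were DKO against WT start (11), DKO against WT satellite (9.78). In 1 fit over all libraries, the call was lost for sgRex1 day 2 YY1 (4.56), sgRex1 day 2 island (8.25), sgRex1 day 2 start (9.33), sgRex1 day 2 upstream (13.2), sgRex1 day 4 start (-9.32), sgZfp281 day 2 upstream (-17.4), sgZfp281 day 4 YY1 (-6.48), sgZfp281 day 4 island (-2.5), sgRex1 interaction YY1 (-7.13), sgRex1 interaction island (-8.63), sgRex1 interaction start (-18.6), sgRex1 interaction upstream (-11.7), sgZfp281 interaction YY1 (7.79), sgZfp281 interaction island (18.9), sgZfp281 interaction start (17.5), sgZfp281 interaction upstream (17.1), DKO against RNF12-KO YY1 (-9.02). A call was gained for sgRnf12 day 3 upstream (11.7), sgZfp36l1 day 4 YY1 (-18), RNF12-KO against WT satellite (7.07), DKO against WT satellite (9.78). In fits to single lines, the call was lost for sgZfp36l1 day 4 start (-8.81), sgZfp280c day 4 satellite (-3.67), sgZfp36l1 KD day 4 against day 2 YY1 (34.3), sgZfp280c KD day 4 against day 2 satellite (4.21). Calls were gained for sgRnf12 day 3 YY1 (25.1), sgRnf12 day 3 upstream (11.7), sgZic3 day 3 start (11). The counts of CpGs were 48 for sgRnf12 day 3, 9 for sgZic3 day 3, 0 for sgZfp36l1 day 4. From plus-strand calls alone, the call was lost for sgZfp280c KD day 4 against day 2 satellite (3.39). The sign changed for sgZfp281 day 4 upstream (0.151). With limma per CpG, the counts of CpGs were 0 for sgRnf12 day 3, 0 for sgZfp36l1 day 4. Without amplicons under 1% of the deepest, the call was lost for sgZfp36l1 day 4 start (-0.679). Calls were gained for sgRnf12 day 3 YY1 (25.1), sgZfp36l1 KD day 4 against day 2 start (18.9). The sign changed for sgZfp280c day 2 start (2.57), sgZfp280c interaction start (-3.18). With the island included in that rule, the call was lost for sgZfp36l1 day 4 start (-0.679), sgZfp281 day 4 island (-2.1), DKO against RNF12-KO YY1 (-9.02). Gained calls were sgRnf12 day 3 YY1 (25.1), sgZfp36l1 KD day 4 against day 2 start (18.9). The sign changed for sgZfp280c day 2 start (2.57), sgZfp280c interaction start (-3.18), sgRex1 day 4 island (1.44).

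Leaving out each library in turn changed a call or sign at least once in the results that follow, given with their lowest and highest values. Ranges were sgRnf12 day 3 start 17.1 to 21.6, sgZic3 day 3 YY1 -4.64 to 0.208, sgZfp36l1 day 2 YY1 -17.5 to 10.1, sgZfp36l1 day 2 satellite -1.59 to 0.522, sgZfp36l1 day 4 YY1 -27.2 to -0.233, sgZfp36l1 day 4 start -17.2 to -3.99, sgZfp36l1 day 4 upstream -21.5 to 0.42, sgZfp280c day 2 start -5.32 to 2.57. Among further results, ranges were sgZfp280c day 4 upstream -1.88 to 1.14, sgZfp280c day 4 satellite -5.04 to -2.67, sgZfp36l1 KD day 4 against day 2 start 6.67 to 15.6, sgZfp280c KD day 4 against day 2 satellite 2.85 to 5.22, sgZfp36l1 interaction start -13.4 to -0.0849, sgZfp36l1 interaction upstream -14.6 to 7.4, sgZfp36l1 interaction satellite -1.03 to 1.09, sgZfp280c interaction start -3.18 to 4.71. Ranges in others were sgZic3 day 3 island -6.28 to 3.74, sgRex1 day 2 YY1 3.96 to 5.5, sgRex1 day 4 YY1 -4.24 to -1.02, sgRex1 day 4 island -1.07 to 0.0616, sgRex1 day 4 upstream 0.941 to 2.29, sgRex1 day 4 satellite -1.39 to 0.998, sgZfp281 day 2 satellite -2.67 to 0.373, sgZfp281 day 4 island -3.08 to -2.05. The next were sgZfp281 day 4 start -2.69 to 0.876, sgRex1 KD day 4 against day 2 start -0.0267 to 5.19, sgRex1 interaction YY1 -8.8 to -5.59, DKO against WT island 17 to 29.3, DKO against WT start 9.65 to 13.3, DKO against WT upstream 6.41 to 10.3, DKO against WT satellite 7.29 to 12.3, DKO against RNF12-KO YY1 -11.4 to -6.66. After these came DKO against RNF12-KO start -9.42 to -7.33, DKO against RNF12-KO count of CpGs 13 to 38, DKO against WT count of CpGs 16 to 39, sgRnf12 day 3 count of CpGs 0 to 9, sgZfp281 day 4 count of CpGs 8 to 22, sgZfp36l1 day 4 count of CpGs 0 to 23.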

Other observations

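Tests chosen after the result was seen were those of relative depth, of whole-library shifts and of a shift of all amplicons in sgZic3, and the tallies of effect sizes and of the order of the amplicons were made after the values were seen. The tests of satellite sequences and strands, of the direction of YY1 core effects and of other splits were set before their values were seen. The order of the amplicons was tallied within lines among libraries with values in all 4, since the days hold different lines. The island was the highest in 0 of 9 dCas9-KRAB libraries at day 2 and 9 of 9 at day 4, but in sgZfp280c in 5 of 5 at day 2 and 4 of 6 at day 4. The YY1 amplicon was the lowest in 9 of 9 and 6 of 9 dCas9-KRAB libraries, and in 5 of 5 and 4 of 6 sgZfp280c libraries. Among plus-strand calls of the upstream amplicon, the CpG at 103483455 was the lowest of 6 in 62 of 62 libraries, with a median of 12.8%.

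The effects on YY1 core CpGs lay above those on the other CpGs of the amplicon, in log2 odds, in 9 of 13 comparisons. The comparisons run in both directions, so a weaker effect on core CpGs would also give mixed signs, and this test does not decide whether the effects differ. The core effect was the smaller in size in 11 of 13 comparisons in log2 odds and in 6 of 13 in points, a tally made after the result was seen over comparisons that share groups, and whether the sizes differ was not tested.

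Single sgZfp36l1 libraries stood far from the other libraries of their group in an amplicon. Few starting molecules or stray reads in amplicons of low relative depth may contribute, which stayed open. Over the 4 Xist amplicons, 29 values under 1% of the deepest amplicon were set against the other 207, which lay a median of 0.889 points from their group median. The ratio of the median distances was 1.69 (one-sided permutation within lines, p = 0.0584) and lay between the bounds set for and against this explanation. Without the island it was 9.11 (6 against 182 values, permutation p = 0.0276), and without the farthest of those 6 as well 6.83 (permutation p = 0.0547). All 6 came from the sgZfp36l1 and sgZfp280c lines, and over the 4 amplicons of a single line the ratio was 6.06 in sgZfp36l1 (4 against 32 values, permutation p = 0.115) and 3.23 in sgZfp280c (12 against 35 values, permutation p = 0.138). In dCas9-KRAB it was 1.28 (13 against 59 values, permutation p = 0.424). Of the 4 libraries that stood apart, 3 lay above that depth, at 11.2%, 1.73% and 6.6%. As a share of the distance in the outlying amplicon, that in the other amplicons had a median of -0.0912. In day 4 control replicate 3 it was -0.0748, which argues against a shift of that whole library. Day 4 knockdown replicates 1 and 3 (-0.108 and -0.454) were set against means that held each other's outlying value, so their shares do not decide. Day 2 knockdown replicate 3 (0.164) also lay above both others upstream and at the start site, there at 75.1% against 60.2% and 60.7%. A shift of that library stays open. No biological explanation was tested.

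Satellite methylation was lower in sgZic3 knockdown than in its control. Within the satellite copies of chromosome 2, which held 73.7% to 77.3% of satellite calls in these libraries, the difference was -10.7 points. From plus-strand calls it was -10.96 points. These values argue against a changed share of those copies or of the strands. A changed mix of sequences within the chromosome 2 copies was not tested. Incomplete conversion raises measured methylation, so only that of the control libraries could give this difference. That, or a shift in all amplicons, stays open. The start-site amplicon was 11.03 points higher without overlap, and passed in the fit to this line alone (adjusted p = 0.0113) but not in the planned fit (adjusted p = 0.228). The YY1 amplicon (-2.17 points) and the island (-1.01 points) lay on the same side as the satellites, by less than their SE. The upstream amplicon was 2.85 points higher in the knockdown (limma adjusted p = 0.737). An effect of the knockdown on the satellites and an unlabelled batch stay open as well, both untested.

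Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few for a share under 0.05. With the real count of CpGs first and the highest of the other splits after it, these were 10 and 0 for sgRnf12, 48 and 0 for sgZfp281 at day 2, 15 and 11 at day 4, 38 and 0 for sgRex1 at day 2 and 11 and 20 at day 4. They were 43 and 0 for RNF12-KO against WT, 39 and 1 for DKO against WT and 37 and 12 for DKO against RNF12-KO. For sgZfp36l1 at day 4 they were 9 and 11, with 3 of 10 splits as large, and for sgRex1 at day 4 2 of 10 were as large. In the others named so far 1 split, the real one, was as large. For sgZic3, sgZfp36l1 at day 2 and sgZfp280c on both days edgeR called 0 CpGs in all 10 splits, with 0 at an unadjusted p under 0.05 and 0 by limma for the real split.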
